A study of Mus musculus with 45 samples.

How the data were processed

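RNA from mouse splenic B2 cells was sequenced before and during culture in 45 libraries that form 15 groups of 3. Per the labels' protocols, B2 cells were enriched by density centrifugation and a CD43-based kit to a purity above 95%, and RNA was extracted with TRIzol and treated with DNase. The TLR culture held irradiated feeder cells with CD40L, LPS at 5 µg/mL, and IL-4 and IL-5 at 50 ng/mL each. The BCR culture held the same feeders and cytokines with F(ab')2 fragments against IgM and IgG at 12 µg/mL. Feeders were removed at day 2, and from day 4 the medium held IL-6 at 10 ng/mL, APRIL at 100 ng/mL, amino acids and lipids. The composition of the LPS culture, and whether replicates came from separate animals, are not given in the sources used here. The sample labels, used here, put wild type LPS and all dEx1A groups in 9-week females and the other groups in 7-week males. The protocol text calls the mice sex- and age-matched. Xist levels went with the labelled sex, and the conflict on age stayed open.

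Per the labels' protocols, libraries were made with the TruSeq Stranded Total RNA kit and read on a NextSeq instrument as single reads of 76 bases. Per the submitters' processing notes, the tools were FastQC 0.11.8, Trim Galore 0.6.0, STAR 2.6.0c, RSEM 1.3.0, R 3.5.1 and DESeq2 1.22.2, and the notes list the builds GRCh38.p12, GRCm38.p6 and mm10 without saying which step used which. The roles of these tools, the annotation, the strand setting and any gene filter are not given in the sources used here. The deposited values are log2 expression per gene, made by the authors from RSEM gene estimates by a variance-stabilising transformation per the file names. They come in 2 tables of 28196 genes, with 21 and 39 columns of 1 sample each, and the 15 columns found in both tables hold identical values. The most frequent value, 3.04, filled 312822 cells and was taken as the value of a count of 0, and the highest value was 23.46. Raw reads and isoform-level values were not used here, so exon 1A of Prdm1 was not measured apart from the rest of the gene.

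Gene symbols, GC content, length and coordinates came from GENCODE M21 (GRCm38), matched by the Ensembl identifiers of the tables. Cnksr3 was left out because 1 of its cells, in day 0 replicate 2, read 0.00, below the value of a count of 0. Genes were kept where the value exceeded the floor by at least 1 in at least 3 samples, which left 19497 genes in the wild type table (21 samples, 14 residual degrees of freedom) and 20331 in the table with both genotypes (39 samples, 26 residual degrees of freedom).

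Reads per gene were recovered by inverting the transformation with an unrounded floor of 3.045, where the recovered values under 20 reads were whole, within 0.1, in 92.6 to 100.0% of cases per library against 20% by chance. Recovered totals are estimates of the reads assigned to genes. Values were deposited to 2 decimals, and genes with few reads are compressed toward the floor, so differences there are understated and their direction rests on few reads. On simulated counts, 100.0% of those under 50 were recovered exactly, with size factors off by at most 0.24%. All 45 pairs of same-group libraries were checked for duplicates, and chi-square per gene between them ran from 4.44 to 134.31, so no pair was a copy. Over 9920 protein-coding genes, the main axis of the spread between replicates held 58.1% of it and had a Spearman rho across genes of 0.88 in size with GC content and 0.32 with length. The GC offset of a library is the median deviation from the mean of all libraries in the most GC-rich 25% of these genes less that in the most GC-poor 25%. The division of the libraries at 20 M reads was made after the values were seen.

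The 23 comparisons were tested with limma 3.58.1 in R 4.3.3. Group means were fitted over all groups of a table, so that groups shared 1 estimate of the spread, followed by empirical Bayes moderation with a trend on the mean. Genes passed at a Benjamini-Hochberg adjusted p below 0.05, two-sided, adjusted within each comparison. Wild type steps and the comparisons of TLR with BCR were tested in the wild type table, and LPS and dEx1A comparisons in the other. For each culture system the change of the genotype difference from day 4 to day 7 was tested as an interaction. Lists were tested with camera at a preset correlation of 0.01, adjusted over 24 lists, and again with the correlation estimated from the data. The lists were fixed before the data were examined, as were the groups, comparisons, tests and alternatives other than those named as later additions. They were transcription factors of B cell and plasma cell fate, mature B cell identity, antigen presentation by MHC class II, plasma cell identity, ER folding, export and degradation, the ATF4 and CHOP amino acid and stress response, cell division, MYC and ribosome biogenesis, germinal centre and class switching, immunoglobulin constant regions, NF-kB targets, interferon-stimulated genes, cholesterol synthesis, glycolysis, oxidative phosphorylation, survival and apoptosis, homing and adhesion, and genes repressed by Blimp-1 in textbooks. Lists of other cells were T cells, myeloid cells, NK cells with basophils or mast cells, erythroid cells with platelets, and fibroblasts for the feeders, and a sex-linked list was added. Counts within a list are given at the adjusted p over all genes and, in parentheses, with the adjustment made over the list alone.

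Genes were named by a fixed rule with 3 parts. Prdm1, Irf4, Xbp1, Pax5, Bach2, Sdc1, Jchain and Mki67 were eligible throughout. The 5 largest rises and 5 largest falls among genes past the threshold were eligible where the groups did not overlap and the mean exceeded the median of the kept genes, leaving out immunoglobulin and T cell receptor segments, provisional names, pseudogenes and sex-linked genes. The condition of no overlap was not applied to the interactions. From each list described, the 2 to 4 members with the smallest adjusted p were eligible. Some eligible genes are not reported here. Any other gene is said to have been chosen after its values were seen.

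Each result was recomputed with no filter, with a stricter filter of 2 above the floor, with samples centred on the median of the genes above the median level (an alternative planned over all kept genes), with only the groups compared in the fit, with the replicate number as a block, and without each replicate in turn. Added after the data were seen were a correction for GC content and length, the same with the block, voom on the recovered reads, and the day 10 BCR group without replicates 1 and 2. The correction regressed each library's deviations from the mean of all libraries on natural splines of GC content (4 degrees of freedom) and log2 length (2), within 10 strata of mean value and with deviations limited to the 5th and 95th percentiles, over 19490 and 20323 genes. The fitted trend less its median was subtracted, so a difference between groups that follows GC content is removed with it. An earlier form without strata was replaced because it shifted the median of all genes. Replicate numbers were checked as a pairing in the 23 comparisons by the correlation of same-numbered residuals, with 0.1 as the bound.

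The fit was tested on simulated data made from the day 7 LPS groups, 19953 genes with 200 changed. It recovered 4 of 50 changes of 0.5 log2 units (8%), 43 at 1, 49 at 2 and 50 at 3. It called 53 unchanged genes, 1 with a mean above 7. With only the 2 groups in the fit, as many changed genes (146) were recovered and 2 unchanged ones called. Of the unchanged lists, 0 of 23 were called, and the changed list had an adjusted p of 5.39e-75. An added GC trend made 6729 unchanged genes pass, against 63 after the correction, which recovered 74% of the changed genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.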

Results

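Mouse splenic B2 cells were profiled before culture and as they turned into antibody-secreting cells in 3 culture systems, in wild type and in mice lacking exon 1A of Prdm1 (dEx1A), the gene of the plasma cell repressor Blimp-1. The 45 RNA-seq libraries formed 15 groups of 3: wild type B cells at day 0, wild type TLR and BCR cultures at days 4, 7 and 10, wild type LPS cultures at days 4 and 7, and dEx1A LPS, TLR and BCR cultures at days 4 and 7. Per the labels, TLR cells grew on CD40L feeders with LPS, IL-4 and IL-5, and BCR cells on the same feeders and cytokines with antibody to surface IgM and IgG. The labels call the cells plasmablasts at days 4 and 7 and plasma cells at day 10. The LPS culture is described only by its label.

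Reads assigned to genes, recovered from the deposited values, ran from 15.17 M to 35.56 M per library with a median of 23.24 M. By group the range in M reads was 20.29 to 21.87 for B cells at day 0, 28.56 to 30.3, 21.99 to 35.56 and 20.47 to 27.97 for wild type TLR at days 4, 7 and 10, and 20.42 to 31.38, 23.48 to 33.95 and 23.76 to 26.42 for wild type BCR. It was 15.49 to 19.39 and 15.58 to 16.74 for wild type LPS at days 4 and 7, 26.12 to 30.08 and 15.17 to 18.71 for dEx1A LPS, 23.26 to 28.12 and 16.34 to 19.54 for dEx1A TLR, and 23.24 to 28.9 and 17.14 to 19.58 for dEx1A BCR. The libraries therefore fell into 2 sets that no group straddled: 15 libraries (wild type LPS at both days and every dEx1A day 7 group) had fewer than 20 M reads, and the other 30 had more. The same 2 sets parted by the GC content of the transcripts they favoured, with offsets of 0.74 to 1.72 in the 15 libraries and −1.93 to 0.61 in the 30. Wild type LPS and all dEx1A mice were 9-week females, and the other wild type mice 7-week males.

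**Figure D1:**
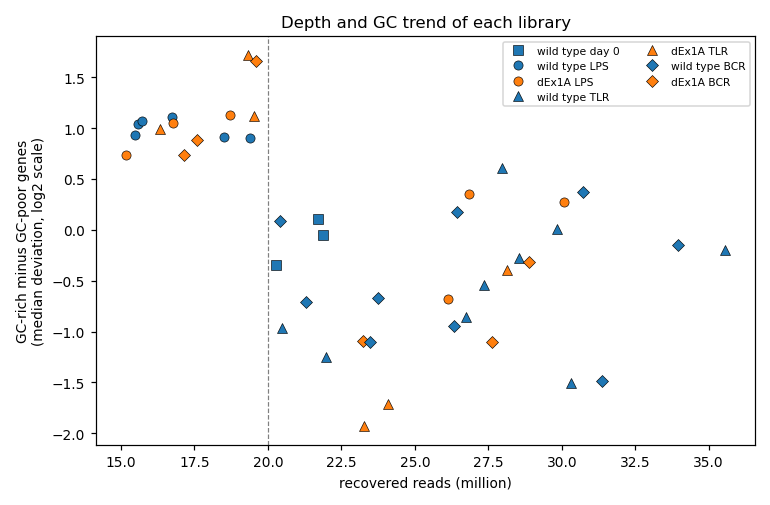
Each point is 1 library: reads assigned to genes (M) against its GC offset, in blue for wild type and orange for dEx1A. The dashed line marks 20 M reads.

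Values were the authors' log2 variance-stabilised expression, so differences are in log2 units and understate changes of weakly expressed genes. Each difference is given with its standard error from limma, every group held 3 libraries, and p was adjusted within each comparison. The labels do not state that the 3 replicates of a group came from separate animals, so the p-values measure the spread between samples. Genes named for the size of their change showed no overlap between the groups compared, meaning that 3 of 3 libraries of each group lay on their own side, which 2 groups of 3 reach by chance in 10% of cases. Prdm1 (ENSMUSG00000038151.13) lies on the minus strand of chromosome 10 at 44437177 to 44528501 of GRCm38, and its values cover the whole gene and do not separate exon 1A.

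By day 4 of the TLR culture of wild type B cells genes of cell division had risen. The largest rise was in Ccl22, a chemokine that attracts T cells, from 5.01 ± 0.48 (mean ± SD) at day 0 to 14.98 ± 0.21. Ighe, the IgE heavy chain locus (8.60 ± 0.41), Socs2, an inhibitor of cytokine signalling (8.40 ± 0.33), and Tnfrsf8, which encodes CD30 (8.33 ± 0.26), also rose. Icosl, a ligand for T cell costimulation (−8.06 ± 0.30), Rgs2, a brake on G protein signalling (−7.51 ± 0.44), and the Fc receptor-like gene Fcrla (−6.86 ± 0.18) were among the largest falls. Prdm1 rose by 3.28 ± 0.31 (adjusted p = 8.59e-08).

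All 28 genes of the cell division list rose by day 4 of the TLR culture, for example the mitotic kinase gene Cdk1 (4.95 ± 0.18) and Rrm2 of nucleotide synthesis (4.29 ± 0.16), with 28 rising in a test adjusted over the list alone (camera adjusted p = 6.44e-18). Cholesterol synthesis rose in 18 of 20 genes and fell in 0 (18 and 0 adjusted over the list alone, adjusted p = 1.29e-10). In mature B cell identity 23 of 24 fell and 1 rose (23 and 1 adjusted over the list alone, adjusted p = 1.14e-12), including Cr2, the complement receptor CD21 (−6.65 ± 0.38). With an estimated correlation and a correction for GC content and length the adjusted p was 0.0663 for cell division and 0.101 for B cell identity. The ATF4 amino acid response rose in 16 of 20 genes and fell in 1, with 3 not passing (16 and 1 adjusted over the list alone), such as asparagine synthetase Asns (6.76 ± 0.21), at an adjusted p = 3.67e-08 and an adjusted p = 0.0632 with an estimated correlation. Homing and adhesion fell in 11 of 20 genes and rose in 4 (11 and 4 adjusted over the list alone), with S1pr1, the receptor for egress from lymphoid tissue, at −6.79 ± 0.21 (adjusted p = 0.000557, adjusted p = 0.05 with an estimated correlation).

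In the TLR culture at day 4, 12 of 13 fibroblast genes were higher than at day 0 and 1 lower (12 and 1 adjusted over the list alone), including Sparc, a matrix protein (3.33 ± 0.37), at an adjusted p = 8.78e-05 and an adjusted p = 0.162 with an estimated correlation. Erythroid and platelet genes fell in 6 of 10 and rose in 0 (7 and 0 adjusted over the list alone), such as haemoglobin Hba-a2 (−6.08 ± 0.54), which shares reads with Hba-a1, at an adjusted p = 0.00583 and an adjusted p = 0.232 with an estimated correlation. In limma, 4852 genes were higher and 4574 lower at day 4 TLR than at day 0.

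Day 4 of the BCR culture was compared with the same 3 day 0 libraries, so resemblance to the TLR comparison is partly built in. Ccl22 again rose most (11.09 ± 0.29), with Socs2 (8.53 ± 0.33) and Timd2, a receptor for ferritin (8.40 ± 0.26). Icosl (−7.73 ± 0.30), Cr2 (−7.65 ± 0.38) and Ly6d, a surface protein of B-lineage cells (−6.81 ± 0.55), were among the largest falls. Prdm1 rose by 3.24 ± 0.31 (adjusted p = 9.07e-08). MYC and ribosome biogenesis genes rose in 16 of 20 and fell in 1 (16 and 1 adjusted over the list alone, adjusted p = 7.58e-06), including the nucleolar Nop56 (1.27 ± 0.10). Interferon-stimulated genes fell in 13 of 21 and rose in 0 (13 lower adjusted over the list alone), among them the RNA sensor gene Ddx58 (−2.65 ± 0.20), at an adjusted p = 0.000181 and an adjusted p = 0.126 with an estimated correlation. Fibroblast genes were higher in 12 of 13 and lower in 1 (12 and 1 adjusted over the list alone), with Sparc at 4.30 ± 0.37 (adjusted p = 2.77e-05, adjusted p = 0.15 with an estimated correlation). In limma, 5092 genes were higher and 4777 lower.

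Between days 4 and 7 antibody genes rose in the wild type TLR culture. Jchain, which joins IgM and IgA units into polymers, rose most, by 7.89 ± 0.41 to 20.15 ± 0.32, followed by the heavy chain genes Ighg3 (6.40 ± 0.40) and Ighg2b (6.14 ± 0.39) and by Thbd, thrombomodulin (6.16 ± 0.25). Thy1, of the fibroblast list for the feeders (−5.29 ± 0.42), CD30 (Tnfrsf8, −5.09 ± 0.26) and the integrin gene Itgb3 (−4.03 ± 0.46) were among the largest falls. Prdm1 rose by 3.40 ± 0.31, Sdc1, the plasma cell surface protein CD138, by 3.70 ± 0.32, and Xbp1, the driver of the secretory response, by 2.23 ± 0.28. Irf4 rose by 1.83 ± 0.30 and Bach2, a repressor of plasma cell fate, rose by 0.79 ± 0.20 (adjusted p = 0.0048). Pax5 was at −0.45 ± 0.20 (adjusted p = 0.0877) and Mki67 at −0.54 ± 0.24 (adjusted p = 0.0873). Pax5 passed with only the groups compared in the fit (adjusted p = 0.0261), and Mki67 after the GC and length correction (−0.85, adjusted p = 0.00163) and without replicate 3 of day 7 TLR (−0.84, adjusted p = 0.00737).

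From day 4 to day 7 of the TLR culture, plasma cell identity genes rose in 23 of 25 and fell in 0 (23 and 0 adjusted over the list alone, adjusted p = 4.09e-16), with the APRIL receptor gene Tnfrsf17 at 4.18 ± 0.32. The list had an adjusted p = 0.0935 with an estimated correlation and the GC correction. ER folding, export and degradation rose in 27 of 28 and fell in 0 (27 and 0 adjusted over the list alone), such as the stress sensor gene Ern1 (3.38 ± 0.27), at an adjusted p = 7.84e-16 and an adjusted p = 0.0783 with an estimated correlation. Immunoglobulin constant regions rose in 11 of 12 and fell in 0 (11 and 0 adjusted over the list alone, adjusted p = 4.16e-12). MYC and ribosome biogenesis fell in 15 of 20 and rose in 0 (16 lower and 1 higher adjusted over the list alone, adjusted p = 2.36e-06). Cell division fell in 26 of 28 and rose in 0 (27 lower adjusted over the list alone), with thymidylate synthase, Tyms, at −2.68 ± 0.17 (adjusted p = 1.83e-13, adjusted p = 0.0506 with an estimated correlation). Glycolysis fell in 14 of 15 and rose in 0 (14 lower adjusted over the list alone), with Pfkp at −1.56 ± 0.12 (adjusted p = 2.66e-06, adjusted p = 0.165 with an estimated correlation). Fibroblast genes fell in 11 of 13 and rose in 1 (12 and 1 adjusted over the list alone), with Sparc at −2.24 ± 0.37 (adjusted p = 8.84e-05, adjusted p = 0.207 with an estimated correlation). In limma, 3451 genes were higher and 3633 lower at day 7.

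From day 4 to day 7 of the BCR culture the heavy chain genes Ighg2b (8.20 ± 0.39) and Igha (6.66 ± 0.53) and Jchain (7.03 ± 0.41) were among the largest rises. Thbd (5.94 ± 0.25) and the macrophage lysozyme Lyz2 (5.83 ± 1.21) also rose. The activation factor Fosb (−3.87 ± 0.75), the interleukin-2 receptor gene Il2ra (−3.44 ± 0.23) and CD30 (Tnfrsf8, −3.55 ± 0.26) were among the largest falls of well expressed genes. Prdm1 rose by 2.71 ± 0.31, Sdc1 by 3.55 ± 0.32 and Bach2 by 1.07 ± 0.20, and Pax5 was at 0.12 ± 0.20 (adjusted p = 0.697).

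In this BCR step, plasma cell identity rose in 21 of 25 and fell in 0 (22 higher adjusted over the list alone, adjusted p = 7.41e-14, and 0.0965 with an estimated correlation and the GC correction). Homing and adhesion rose in 12 of 20 and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 1.12e-05), such as the chemokine receptor gene Ccr6 (4.47 ± 0.21). Transcription factors of B cell and plasma cell fate rose in 10 of 22 and fell in 0 (12 higher adjusted over the list alone, adjusted p = 2.46e-05, and 0.139 with an estimated correlation and the GC correction), among them the germinal centre repressor Bcl6 (2.17 ± 0.14). Genes of mature B cell identity rose in 16 of 24 and fell in 1 (18 and 1 adjusted over the list alone), with Cd72 at 2.33 ± 0.21 (adjusted p = 2.45e-06, adjusted p = 0.157 with an estimated correlation). Cholesterol synthesis fell in 15 of 20 and rose in 0 (15 lower adjusted over the list alone, adjusted p = 2.1e-11), with Fdft1 at −1.71 ± 0.13. Myeloid genes rose in 7 of 15 and fell in 0 (7 higher adjusted over the list alone), including Cst3, cystatin C (2.07 ± 0.26), at an adjusted p = 0.000111 and an adjusted p = 0.301 with an estimated correlation. In limma, 2976 genes were higher and 2962 lower.

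From day 7 to day 10 genes of sterol synthesis fell in the wild type TLR culture, with Prdm1 at 0.28 ± 0.31 (adjusted p = 0.642). Scd2, which desaturates fatty acids (−2.50 ± 0.14), and the inhibitory receptor gene Tigit (−2.69 ± 0.21) were among the largest falls. Ighg2b rose by 3.65 ± 0.39 to 17.64 ± 0.31, and other large rises were in the macrophage-type genes Ccl6, a chemokine (4.64 ± 1.10), Lgals3, galectin-3 (4.16 ± 0.99), and Hmox1, which degrades haem (3.98 ± 0.71). Bach2 fell by 1.69 ± 0.20, Pax5 by 1.18 ± 0.20 and Mki67, a marker of cycling cells, by 1.08 ± 0.24. Jchain was at −0.11 ± 0.41 (adjusted p = 0.908). The calls of Ccl6, Lgals3 and Mki67 ended with only the groups compared in the fit (adjusted p = 0.12, 0.128 and 0.0763) and that of Mki67 without replicate 3 of day 7 TLR (−0.77, adjusted p = 0.058). Those of Ccl6 and Lgals3 also ended with voom on recovered reads (adjusted p = 0.0898 and 0.0681) and without replicate 1 or 3 of day 7 TLR or replicate 2 of day 10 TLR (2.76 to 4.31, adjusted p = 0.0605 to 0.071).

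Cholesterol synthesis fell in 14 of 20 genes and rose in 0 in this late TLR step (16 lower adjusted over the list alone, adjusted p = 3.37e-18). Mature B cell identity fell in 14 of 24 and rose in 0 (14 lower adjusted over the list alone), with the low-affinity IgE receptor gene Fcer2a at −2.20 ± 0.19 (adjusted p = 7.36e-11, adjusted p = 0.062 with an estimated correlation). Cell division fell in 13 of 28 and rose in 0 (18 lower adjusted over the list alone), with Aurkb at −1.38 ± 0.19 (adjusted p = 4.72e-13, adjusted p = 0.062 with an estimated correlation). Myeloid genes rose in 6 of 15 and fell in 1 (7 and 1 adjusted over the list alone), with Cst3 at 1.25 ± 0.26 (adjusted p = 0.000903, adjusted p = 0.441 with an estimated correlation). In limma, 685 genes were higher and 914 lower at day 10, 1599 in all. That total was 704 with only the groups compared in the fit (51.8% higher against 42.8%), 2800 after the GC and length correction and 1060 with voom on recovered reads. Without replicate 1 or 3 of day 7 TLR it was 911 or 781, and without replicate 2 of day 10 TLR 1047.

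From day 7 to day 10 of the BCR culture the lysosomal protease Ctsl (5.73 ± 0.78), the chemokine Ccl6 (5.59 ± 1.10), osteopontin, Spp1 (5.46 ± 1.10), and Lyz2 (5.05 ± 1.21) were among the largest rises. Lifr, a receptor for leukaemia inhibitory factor (−2.74 ± 0.22), and the lymphotoxin gene Lta (−2.34 ± 0.20) were among the largest falls of well expressed genes. Bach2 and Pax5 fell by 1.80 ± 0.20 each, and Prdm1 was at 0.41 ± 0.31 (adjusted p = 0.417). Without replicates 1 and 2 of day 10 BCR Prdm1 passed (1.29, adjusted p = 0.0197) and the calls of Ccl6 (3.76, adjusted p = 0.158), Spp1 (3.22, adjusted p = 0.215) and Lyz2 (3.03, adjusted p = 0.321) ended, and that of Lyz2 also with only the groups compared in the fit (adjusted p = 0.059).

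Lyz2 read 16.7, 16.4 and 13.5 in the 3 day 10 BCR libraries and 9.4, 14.9 and 12.1 in the 3 day 10 TLR libraries. Myeloid genes rose from day 7 to day 10 of the BCR culture in 8 of 15 and fell in 1 (9 and 1 adjusted over the list alone), with the macrophage receptor gene Adgre1 at 3.01 ± 0.64 (adjusted p = 4.36e-05, adjusted p = 0.246 with an estimated correlation). The call of Adgre1 ended with only the groups compared in the fit (adjusted p = 0.0705) and without replicates 1 and 2 of day 10 BCR (1.29, adjusted p = 0.344). Genes repressed by Blimp-1 in textbooks fell in 11 of 13 and rose in 0 (11 lower adjusted over the list alone, adjusted p = 3.79e-13), including the follicle homing receptor gene Cxcr5 (−2.20 ± 0.19). Mature B cell identity fell in 16 of 24 and rose in 0 (17 lower adjusted over the list alone, adjusted p = 1.83e-15). For both lists the adjusted p was 0.078 with an estimated correlation and the GC correction. Cholesterol synthesis fell in 14 of 20 and rose in 0 (16 lower adjusted over the list alone, adjusted p = 1.06e-12). In limma, 2101 genes were higher and 1152 lower, 3253 in all. That total was 166 with only the groups compared in the fit and 1884 without replicate 1 of day 10 BCR.

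Over the whole TLR course the day 10 cells carried an immunoglobulin-dominated transcriptome. Ighg1, the IgG1 heavy chain, rose by 15.12 ± 0.59 to 23.10 ± 0.31, Ighg3 by 11.60 ± 0.40, Jchain by 10.58 ± 0.41 and Prdm1 by 6.97 ± 0.31 (adjusted p = 4.8e-12). Cr2 fell by 7.35 ± 0.38, Icosl by 6.58 ± 0.30 and the immediate early gene Nr4a1 by 5.37 ± 0.26. ER folding, export and degradation rose in 27 of 28 and fell in 0 (28 higher adjusted over the list alone), with Sec24d, a coat protein of ER exit vesicles, at 5.17 ± 0.20 (adjusted p = 1.09e-19, adjusted p = 0.0848 with an estimated correlation). Antigen presentation by MHC class II fell in 9 of 13 and rose in 2 (9 and 2 adjusted over the list alone), with the class II chaperone gene H2-Ob at −2.48 ± 0.16 (adjusted p = 0.0013, adjusted p = 0.247 with an estimated correlation). Reads from immunoglobulin genes made up 58.74 to 66.47% of the day 10 TLR libraries against 1.94 to 2.01% at day 0. In limma, 4461 genes were higher and 4509 lower.

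Over the BCR course, tested against the same day 0 libraries, Ighg1 rose by 13.94 ± 0.59, Gpnmb, a lysosomal membrane protein of macrophages, by 12.40 ± 0.98, Spp1 by 10.52 ± 1.10 and Jchain by 9.35 ± 0.41. Prdm1 rose by 6.37 ± 0.31. Cr2 (−7.60 ± 0.38) and Klf2, a quiescence factor (−5.12 ± 0.25), fell. Immunoglobulin reads made up 24.95 to 52.22% of the day 10 BCR libraries. Myeloid genes were higher in 12 of 15 and lower in 0 (12 higher adjusted over the list alone), with Ly6g at 3.97 ± 0.36 (adjusted p = 0.00234, adjusted p = 0.344 with an estimated correlation). In limma, 5760 genes were higher and 4447 lower.

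**Figure D2:**
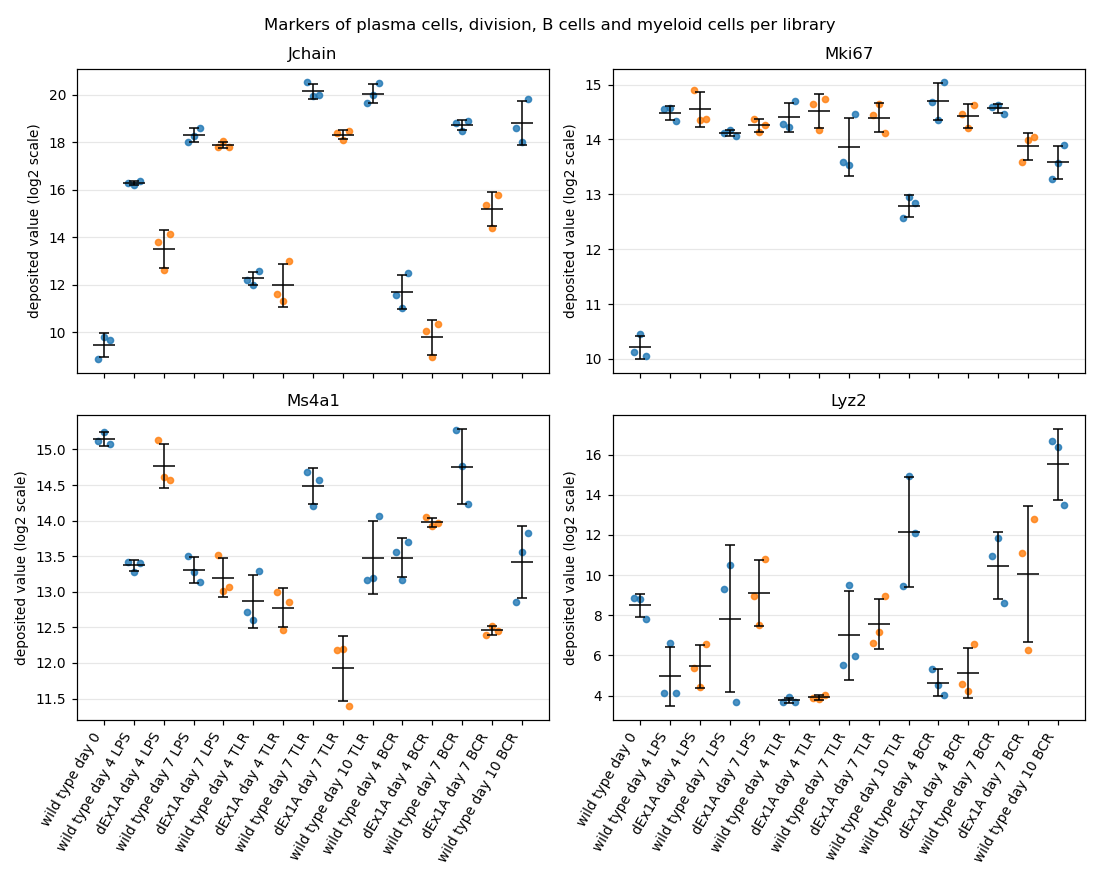
Expression in log2 units of Jchain, Mki67, Ms4a1 and Lyz2 in every group, with 1 point per library in blue for wild type and orange for dEx1A. Black bars give mean ± SD.

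At day 4 interferon genes were higher in TLR than in BCR cells of wild type mice, with Prdm1 at 0.04 ± 0.31 (adjusted p = 0.986). Flt3, a growth factor receptor of early progenitors, was higher in TLR cells by 5.93 ± 0.17 (10.02 ± 0.08 against 4.09 ± 0.27), as were the interferon-inducible Ifi211 (4.48 ± 0.23) and Ly6a, which encodes Sca-1 (4.40 ± 0.21). Lpl, a lipase (−5.70 ± 1.01), and the calcium channel gene Ryr2 (−2.92 ± 0.32) were lower in TLR cells. Interferon-stimulated genes were higher in 18 of 21 and lower in 0 (19 higher adjusted over the list alone, adjusted p = 1.74e-21), such as Ifit1, which binds viral RNA (2.20 ± 0.28). MYC and ribosome biogenesis genes were lower in 6 of 20 and higher in 1 (11 and 1 adjusted over the list alone, adjusted p = 5.24e-07), with the RNA polymerase I subunit gene Polr1b at −0.86 ± 0.15. The ATF4 response was higher in 8 of 20 and lower in 0 (11 higher adjusted over the list alone), with Vldlr at 2.38 ± 0.28 (adjusted p = 2.96e-09, adjusted p = 0.0892 with an estimated correlation). In limma, 839 genes were higher and 637 lower, 1476 in all. The total was 2730 after the GC and length correction, 789 without replicate 1 of day 4 TLR and 873 without replicate 1 of day 4 BCR.

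At day 7 the TLR and BCR cells were compared in the same way. Ly6a (4.24 ± 0.21), Ighg3 (4.07 ± 0.40), Ighe (4.02 ± 0.41) and the complement-related receptor gene Cd93, a marker of plasma cell upkeep (3.50 ± 0.35), were higher in TLR. Il9r, the interleukin-9 receptor (−3.18 ± 0.27), and the T cell kinase gene Lck (−2.56 ± 0.32) were lower. Prdm1 was at 0.73 ± 0.31 (adjusted p = 0.192, and 0.0307 with only the groups compared in the fit). ER folding, export and degradation genes were higher in 11 of 28 and lower in 0 (20 higher adjusted over the list alone), with the stress sensor gene Atf6 at 0.98 ± 0.19 (adjusted p = 2.78e-14, adjusted p = 0.145 with an estimated correlation). Interferon-stimulated genes were higher in 7 of 21 and lower in 0 (13 higher adjusted over the list alone, adjusted p = 2.87e-10), with Mx1 at 1.18 ± 0.18. Fibroblast genes were lower in 5 of 13 and higher in 0 (9 lower adjusted over the list alone), with Sparc at −2.22 ± 0.37 (adjusted p = 1.04e-06, adjusted p = 0.145 with an estimated correlation). In limma, 735 genes were higher and 488 lower, 1223 in all. The total was 2246 after the GC and length correction, 428, 780 and 661 without replicate 1, 2 or 3 of day 7 TLR, and 719 and 503 without replicate 1 or 2 of day 7 BCR.

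At day 10 some antibody genes were higher in wild type TLR than in BCR cells. Ighg3 was higher by 5.03 ± 0.40, Ighe by 4.09 ± 0.41, Slpi, a protease inhibitor of secretory cells, by 3.31 ± 0.52 and Ighm by 2.71 ± 0.33. Il9r (−2.48 ± 0.27) and the sodium channel gene Scn3a (−2.76 ± 0.30) were lower, Prdm1 was at 0.60 ± 0.31 (adjusted p = 0.214; 1.04, adjusted p = 0.00575 without replicate 3 of day 10 BCR), and Irf4 was higher by 1.08 ± 0.30 (adjusted p = 0.0242). Plasma cell identity genes were higher in 10 of 25 and lower in 0 (17 and 1 adjusted over the list alone), with the redox chaperone gene Txndc5 at 1.35 ± 0.28 (adjusted p = 2.45e-08, adjusted p = 0.284 with an estimated correlation). Cell division genes were lower in 18 of 28 and higher in 0 (21 lower adjusted over the list alone), with Cdk1 at −1.01 ± 0.18 (adjusted p = 1.96e-09, adjusted p = 0.284 with an estimated correlation). Myeloid genes were lower in 4 of 15 and higher in 1 (12 and 2 adjusted over the list alone), with Adgre1 at −2.08 ± 0.64 (adjusted p = 0.0156, adjusted p = 0.616 with an estimated correlation, 0.0635 after the GC correction). With only the groups compared in the fit, none of these calls remained, with an adjusted p from 0.0733 for Ighg3 to 0.382 for Adgre1. Without replicates 1 and 2 of day 10 BCR those of Irf4 (0.13), Txndc5 (0.87), Cdk1 (−0.64) and Adgre1 (−0.36) ended (adjusted p = 0.269 to 0.865). That of Adgre1 ended with no filter (adjusted p = 0.0563) and with voom (adjusted p = 0.0548). Those of Irf4 and Adgre1 also ended without replicate 1 or 3 of day 10 TLR or replicate 1 or 2 of day 10 BCR (adjusted p = 0.0624 to 0.217).

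In limma, 837 genes were higher and 1966 lower in day 10 TLR than in day 10 BCR, 2803 in all, of which 29.9% were higher. This count rested on few libraries. It was 1 with only the groups compared in the fit and 1684 with voom, against 4506 after the GC and length correction. Without replicate 1, 2 or 3 of day 10 BCR it was 1210, 650 or 5484, and without replicate 1 or 3 of day 10 TLR 985 or 1477.

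Wild type LPS cells held Prdm1 at 12.52 ± 0.17 (mean ± SD) on day 4, and from day 4 to day 7 heavy chain genes rose. Ighg1 (5.23 ± 0.46), Ighg3 (4.17 ± 0.39) and Ighg2b (3.85 ± 0.48) rose most, with Ccl22 (3.65 ± 0.24) and Jchain (2.00 ± 0.41). Map2, a microtubule protein (−2.32 ± 0.36), the sterol exporter gene Abcg1 (−1.84 ± 0.25) and Mybl1, a germinal centre factor (−1.63 ± 0.34), fell. Prdm1 was at 0.09 ± 0.28 (adjusted p = 0.944). Cell division fell in 10 of 28 and rose in 0 (18 lower adjusted over the list alone, adjusted p = 1.63e-12, and 0.0505 with an estimated correlation and the GC correction), with Ccnb1, the mitotic cyclin, at −0.75 ± 0.13. Plasma cell identity rose in 6 of 25 and fell in 0 (10 higher adjusted over the list alone), with Slpi at 2.08 ± 0.46 (adjusted p = 9.87e-05, adjusted p = 0.315 with an estimated correlation). In limma, 965 genes were higher and 743 lower, 1708 in all. The total was 3623 with only the groups compared in the fit, 3412 after the GC and length correction (1625 higher and 1787 lower), 1016 without replicate 2 of day 4 LPS and 1073 without replicate 3 of day 7 LPS.

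Prdm1 read 6.01, 6.54 and 6.95 at day 0. Wild type TLR at days 4, 7 and 10 read 9.83, 9.66 and 9.86, then 13.43, 13.04 and 13.09, then 13.43, 13.46 and 13.51. Wild type BCR read 9.68, 9.32 and 10.23, then 12.48, 12.33 and 12.56, then 12.71, 12.15 and 13.75, and wild type LPS 12.55, 12.68 and 12.34 at day 4 and 12.4, 12.66 and 12.77 at day 7. The dEx1A libraries read 9.93, 9.6 and 10.01 (day 4 LPS), 11.1, 11.32 and 11.22 (day 7 LPS), 9.91, 9.71 and 10.61 (day 4 TLR), 11.9, 11.81 and 11.72 (day 7 TLR), 8.45, 7.27 and 8.82 (day 4 BCR) and 10.02, 10.1 and 10.8 (day 7 BCR). Prdm1 was thus lower in dEx1A in 5 of 6 comparisons: −2.68 ± 0.28 and −1.40 ± 0.28 in LPS at days 4 and 7, −1.38 at day 7 TLR, and −1.56 and −2.15 in BCR. At day 4 TLR it was at 0.29 (adjusted p = 0.571). Only LPS day 7 was matched for sex, age and library set.

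**Figure D3:**
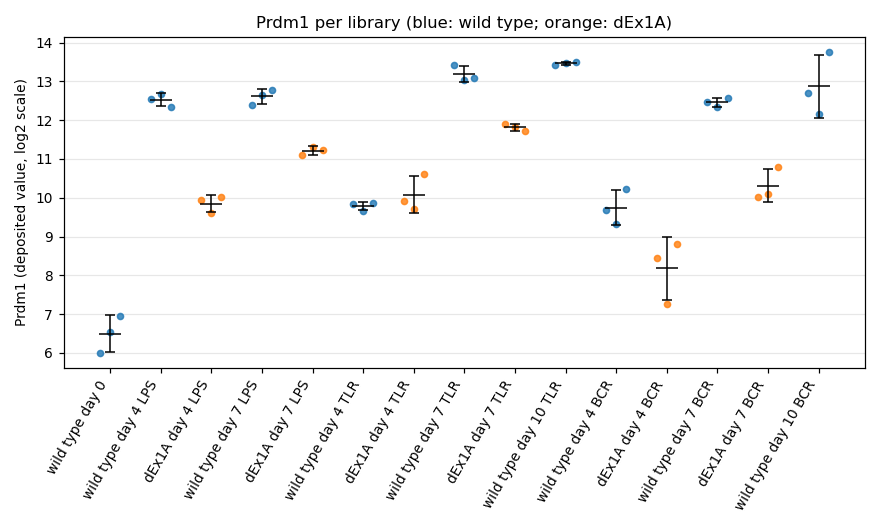
Prdm1 expression in log2 units in every group, with 1 point per library in blue for wild type and orange for dEx1A. Black bars give mean ± SD.

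In LPS cultures at day 4, several plasma cell genes were lower in dEx1A than in wild type. Slpi (−4.68 ± 0.46), the lipid carrier gene Apoe (−4.70 ± 0.33) and the interferon regulator gene Irf7 (−3.63 ± 0.28) were among the most reduced, with Jchain at −2.77 ± 0.41, Sdc1 at −2.26 ± 0.29 and Xbp1 at −1.57 ± 0.17. Tnfrsf26, a TNF family decoy receptor, was low only in wild type LPS groups. It read 3.04 ± 0.00 (the floor) in wild type and 8.07 ± 0.26 in dEx1A. Anxa2, a membrane-binding annexin (2.80 ± 0.45), and the glycosyltransferase gene B3gnt5 (2.60 ± 0.36) were also higher. So was Amd2 (2.83 ± 0.36), a close copy of Amd1 with uncertain reads. Pax5 was higher by 0.93 ± 0.21 and Bach2 by 0.76 ± 0.16.

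Plasma cell identity genes were lower in dEx1A at day 4 LPS in 18 of 25 and higher in 1 (18 and 1 adjusted over the list alone), with Txndc5 at −2.14 ± 0.24 (adjusted p = 9.06e-12, adjusted p = 0.174 with an estimated correlation). ER folding, export and degradation genes were lower in 21 of 28 and higher in 1 (23 and 2 adjusted over the list alone), with Herpud1 of ER-associated degradation at −1.38 ± 0.15 (adjusted p = 2.45e-12, adjusted p = 0.199 with an estimated correlation). Genes repressed by Blimp-1 in textbooks were higher in 6 of 13 and lower in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0334, adjusted p = 0.562 with an estimated correlation). Immunoglobulin reads made up 2.44 to 4.63% of dEx1A and 14.12 to 15.52% of wild type libraries. In limma, 2555 genes were higher and 2402 lower, 4957 in all, and 2894 without replicate 1 of dEx1A day 4 LPS. The 2 groups came from different library sets, so genotype and set cannot be told apart here, while sex and age were matched.

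At day 7 of LPS, where both groups came from the same library set and were matched for sex and age, the gap in secretory genes was narrower. Prdm1 remained lower (−1.40 ± 0.28, adjusted p = 0.000949), but Jchain was at −0.42 ± 0.41 (adjusted p = 0.746), Xbp1 at −0.01 ± 0.17 (adjusted p = 1.0) and Sdc1 at 0.79 ± 0.29 (adjusted p = 0.112), and Irf4 was higher (0.84 ± 0.18). Sdc1 passed with only the groups compared in the fit (adjusted p = 0.027) and after the GC and length correction (0.83, adjusted p = 0.0213). Anxa2 (4.62 ± 0.45), the DNA sensor gene Ifi211 (4.05 ± 0.33) and Tigit (2.88 ± 0.27) were higher in dEx1A. So was Tnfrsf26 (4.63 ± 0.23), low only in wild type LPS. Whether the wild type LPS mice came from another source was not tested, so differences in this comparison need not come from genotype. Ighg2c, the IgG2c heavy chain (−3.57 ± 0.47), the membrane repair gene Myof (−3.52 ± 0.42) and Apoe (−2.93 ± 0.33) were lower. So were Tpm3-rs7 (−3.81 ± 0.17) and Rps3a2 (−3.45 ± 0.22), whose reads, shared with near-identical copies, are uncertain.

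The plasma cell identity list was higher in dEx1A day 7 LPS in 5 of 25 and lower in 3 (6 and 3 adjusted over the list alone, adjusted p = 0.538), including Cd93 at −1.84 ± 0.29 and Cd28, a costimulatory receptor of long-lived plasma cells, at 2.11 ± 0.39. The list of mature B cell identity was lower in 5 of 24 and higher in 0 (6 lower adjusted over the list alone), with Fcer2a at −2.20 ± 0.18 (adjusted p = 0.0368, adjusted p = 0.937 with an estimated correlation). In limma, 671 genes were higher and 769 lower, 1440 in all, and 2432 after the GC and length correction.

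The change of the genotype difference from day 4 to day 7 in LPS was positive for secretory genes: the dEx1A cells gained more than wild type. It was 3.05 ± 0.41 for Sdc1, 2.36 ± 0.58 for Jchain, 1.56 ± 0.24 for Xbp1, 1.61 ± 0.25 for Irf4, 4.09 ± 0.90 for Igha and 3.20 ± 0.41 for Gpx3, a secreted peroxidase. For Prdm1 it was 1.28 ± 0.40 (adjusted p = 0.0524), and it passed after the GC and length correction (1.40, adjusted p = 0.0105), with voom (adjusted p = 0.0348), with only the groups compared in the fit (adjusted p = 0.00342), with the stricter filter (adjusted p = 0.0433) and with a replicate block (adjusted p = 0.0248). For Fcer2a it was −2.61 ± 0.26. The call of Jchain ended without replicate 2 of dEx1A day 4 (1.91, adjusted p = 0.0551). Plasma cell identity moved up in 16 of 25 and down in 0 (19 up adjusted over the list alone, adjusted p = 6.92e-17), with Epcam at 2.71 ± 0.36. ER folding, export and degradation moved up in 13 of 28 and down in 0 (21 up adjusted over the list alone), with the translocon gene Sec61a1 at 1.48 ± 0.23 (adjusted p = 1.08e-16, adjusted p = 0.0523 with an estimated correlation). In limma, 671 genes moved up and 443 down, 1114 in all, 60.2% upward and 44.9% after the GC and length correction. The total was 1923 with only the groups compared in the fit, 2072 after the GC and length correction, and 628, 647 and 722 without replicate 1 of dEx1A day 4, replicate 1 of wild type day 7 or replicate 3 of dEx1A day 7. The 4 groups lay in different library sets, so this change cannot be told apart from the set.

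In TLR cultures at day 4 Prdm1 was at 0.29 ± 0.28 (adjusted p = 0.571) and the genotypes differed in other genes. Cep85, a centrosomal protein, was lower in dEx1A (−3.11 ± 0.27, 9.42 ± 0.19 against 12.53 ± 0.35), as were Egln3, an oxygen-sensing hydroxylase (−1.92 ± 0.37), and the long noncoding RNA gene Mirt1 (−1.64 ± 0.23). Amd2 (2.29 ± 0.36, uncertain as above), the scavenger receptor gene Cd36 (2.27 ± 0.35) and Rgs1 (1.64 ± 0.41) were higher. Jchain was at −0.29 ± 0.41 (adjusted p = 0.728). MYC and ribosome biogenesis genes were higher in 9 of 20 and lower in 0 (11 higher adjusted over the list alone, adjusted p = 4.62e-09), such as Wdr12 of ribosome assembly (0.84 ± 0.12). Glycolysis genes were lower in 6 of 15 and higher in 0 (12 lower adjusted over the list alone), with Pfkp at −0.83 ± 0.11 (adjusted p = 4.62e-09, adjusted p = 0.0705 with an estimated correlation). The sex-linked list was lower in 4 of 5 and higher in 1 (4 and 1 adjusted over the list alone, adjusted p = 1.93e-15), with Ddx3y of the Y chromosome at −8.27 ± 0.18 and Xist at 11.69 ± 0.32. The dEx1A mice were female, and the wild type mice male and 2 weeks younger.

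In limma, 830 genes were higher and 639 lower in dEx1A day 4 TLR, 1469 in all, of which 56.5% were higher. The total was 29 with only the groups compared in the fit (24.1% higher), where the calls of Egln3 (adjusted p = 0.109), Mirt1 (0.104), Rgs1 (0.084), Wdr12 (0.0765) and Pfkp (0.0787) ended, and 2381 after the GC and length correction. Without replicate 1, 2 or 3 of wild type day 4 TLR it was 479, 596 or 3198 (46.6% higher in the last), and without replicate 1, 2 or 3 of dEx1A day 4 TLR 845, 2988 (47% higher) or 521. Rgs1 was at 1.48 to 1.54 (adjusted p = 0.0675 to 0.0751) without replicate 1 or 2 of wild type or replicate 3 of dEx1A.

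By day 7 of TLR the dEx1A cells had less Prdm1 (−1.38 ± 0.28, adjusted p = 0.000145), less Jchain (−1.83 ± 0.41), less Xbp1 (−1.11 ± 0.17) and also less Bach2 (−2.41 ± 0.16) and Pax5 (−1.15 ± 0.21), while Sdc1 was at 0.31 ± 0.29 (adjusted p = 0.391). Anxa2 (6.32 ± 0.45) and the cell cycle inhibitor gene Cdkn2a (5.91 ± 0.45) were higher. So were Junb, an AP-1 factor (5.44 ± 0.52), Mif, a cytokine (5.35 ± 0.71), and Rpl36, a ribosomal protein with near-identical copies and so uncertain (6.05 ± 0.94). Cep85 (−4.40 ± 0.27), the germinal centre GTPase gene Nuggc (−3.83 ± 0.28) and Serpinb1a, an inhibitor of neutrophil proteases (−3.80 ± 0.25), were lower. After the GC and length correction the values were 3.93 for Cdkn2a, 3.26 for Junb, 2.34 for Mif, 3.46 for Rpl36 and −2.02 for Xbp1. The median difference of all genes was −0.04 before and −0.11 after it.

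Cell division genes were higher in dEx1A day 7 TLR in 24 of 28 and lower in 0 (24 higher adjusted over the list alone), with Aurkb at 1.31 ± 0.12 (adjusted p = 1.07e-09, adjusted p = 0.0721 with an estimated correlation). ER folding, export and degradation genes were lower in 17 of 28 and higher in 4 (17 and 4 adjusted over the list alone), with Sel1l at −1.62 ± 0.17 (adjusted p = 0.0116, adjusted p = 0.61 with an estimated correlation). Mature B cell identity was lower in 15 of 24 and higher in 3 (15 and 3 adjusted over the list alone), with Ms4a1, which encodes CD20, at −2.56 ± 0.23 (adjusted p = 4.81e-05, adjusted p = 0.157 with an estimated correlation). MYC and ribosome biogenesis was higher in 12 of 20 and lower in 1 (12 and 1 adjusted over the list alone), with Myc itself at 3.66 ± 0.18 (adjusted p = 0.00034, adjusted p = 0.0721 with an estimated correlation). In limma, 5322 genes were higher and 5827 lower, and 3726 and 6065 after the GC and length correction. By at least 1, 3013 were higher and 2254 lower, and after it 1227 and 1589. Sex, age and library set all differed between these 2 groups and cannot be told apart from genotype.

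In TLR cultures the genotype difference grew from day 4 to day 7: by −1.67 ± 0.40 for Prdm1 (adjusted p = 0.000979), −2.59 ± 0.22 for Bach2, −1.11 ± 0.24 for Xbp1 and −1.54 ± 0.58 for Jchain (adjusted p = 0.0286). Large upward changes were in Rpl36 (7.72 ± 1.33, uncertain as above), Anxa2 (6.94 ± 0.64), Mif (6.64 ± 1.00) and Junb (6.18 ± 0.73). Large downward ones were in mt-Atp6, a mitochondrial subunit of ATP synthase (−3.59 ± 0.84), Serpinb1a (−3.51 ± 0.36) and Cr2 (−3.30 ± 0.39). After the GC and length correction the values were 4.29 for Rpl36, 2.79 for Mif, 3.44 for Junb, −2.13 for Cr2, −2.33 for Xbp1 and −0.78 for Jchain, whose call ended (adjusted p = 0.268). It also ended without replicate 1 or 2 of wild type day 4, replicate 1 of wild type day 7, replicate 3 of dEx1A day 4 or replicate 2 of dEx1A day 7 (−1.02 to −1.51, adjusted p = 0.0501 to 0.142). Glycolysis moved up in 12 of 15 and down in 0 (12 up adjusted over the list alone), with Pfkp at 1.80 ± 0.16 (adjusted p = 6.64e-06, adjusted p = 0.339 with an estimated correlation). In limma, 4950 genes moved up and 5094 down, 49.3% upward and 39.2% after the GC and length correction, across 2 library sets.

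In BCR cultures at day 4, dEx1A cells had less Prdm1 (−1.56 ± 0.28, adjusted p = 0.000907) and less Jchain (−1.91 ± 0.41). Cep85 (−2.85 ± 0.27), the vascular growth factor gene Vegfa (−1.98 ± 0.31) and the amino acid transporter gene Slc7a3 (−1.66 ± 0.21) were lower. Ccl3, an inflammatory chemokine (2.37 ± 0.27), Lpl (1.93 ± 0.46), Cd36 (1.96 ± 0.35) and Amd2 (2.39 ± 0.36, uncertain as above) were higher. Plasma cell identity genes were lower in 3 of 25 and higher in 0 (7 lower and 1 higher adjusted over the list alone), with Cd93 at −1.28 ± 0.29 (adjusted p = 1.42e-07, adjusted p = 0.104 with an estimated correlation). The ATF4 response was lower in 6 of 20 and higher in 0 (7 lower adjusted over the list alone), with Asns at −0.90 ± 0.17 (adjusted p = 1.96e-08, adjusted p = 0.104 with an estimated correlation). The sex-linked list was again lower in 4 of 5 and higher in 1 (4 and 1 adjusted over the list alone, adjusted p = 4.51e-28), with Ddx3y at −8.20 ± 0.18. With only the groups compared in the fit the calls of Prdm1 (adjusted p = 0.212), Jchain (0.167), Asns (0.135), Cd93 (0.101), Slc7a3 (0.076), Cd36 (0.0739) and Amd2 (0.071) ended. Without replicate 3 of wild type or replicate 2 of dEx1A those of Jchain (−1.52 and −1.49), Cd93 (−1.17 and −1.12) and Lpl ended (adjusted p = 0.0674 to 0.12). The call of Lpl also ended without replicate 1 or 2 of wild type or 3 of dEx1A, and that of Cd93 without replicate 1 of dEx1A (adjusted p = 0.0533 to 0.0841). In limma, 242 genes were higher and 136 lower, 378 in all. The total was 103 with only the groups compared in the fit, 734 after the GC and length correction and 223 without replicate 1 of wild type day 4 BCR. Without replicate 2 or 3 of dEx1A day 4 BCR it was 192 or 223.

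At day 7 of BCR the dEx1A cells were poor in Prdm1 (−2.15 ± 0.28, adjusted p = 2.52e-07) and in antibody transcripts, with Jchain at −3.54 ± 0.41, Irf4 at −1.20 ± 0.18, Xbp1 at −1.23 ± 0.17 and Sdc1 at −1.26 ± 0.29. Bach2 was also lower (−3.63 ± 0.16), as were the calcium channel gene Cacna1e (−4.99 ± 0.26), Nuggc (−4.83 ± 0.28) and Cep85 (−4.22 ± 0.27). Higher were Nov, a matricellular protein (5.32 ± 0.25), Thy1, of the fibroblast list for the feeders (4.83 ± 0.32), Cdkn2a (4.34 ± 0.45) and CD30 (Tnfrsf8, 4.30 ± 0.20). Mki67 was lower (−0.69 ± 0.21, adjusted p = 0.0074), but after the GC and length correction it was at 0.12 (adjusted p = 0.554) and Xbp1 at −1.95. Without replicate 1 of dEx1A day 7, Mki67 was at −0.55 (adjusted p = 0.0579).

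Plasma cell identity genes were lower in dEx1A day 7 BCR in 21 of 25 and higher in 0 (22 lower adjusted over the list alone), with Txndc5 at −2.20 ± 0.24 (adjusted p = 1.97e-08, adjusted p = 0.0852 with an estimated correlation). Immunoglobulin constant regions were lower in 10 of 12 and higher in 1 (10 and 2 adjusted over the list alone), with Igkc, the kappa chain, at −2.37 ± 0.34 (adjusted p = 0.00166, adjusted p = 0.244 with an estimated correlation). Reads from immunoglobulin genes made up 4.18 to 8.96% of dEx1A against 22.08 to 37.21% of wild type libraries. Cell division was higher in 23 of 28 and lower in 1 (23 and 1 adjusted over the list alone, adjusted p = 8.88e-10), with Tyms at 1.94 ± 0.14. MYC and ribosome biogenesis was higher in 17 of 20 and lower in 1 (18 and 1 adjusted over the list alone, adjusted p = 3.8e-07), with Odc1 at 1.60 ± 0.10. Of the fibroblast list 2 of 14 genes were higher and 2 lower (2 and 0 adjusted over the list alone, adjusted p = 0.835). In limma, 5248 genes were higher and 5082 lower, 10330 in all (4744 and 5352 after the GC and length correction), and 6726 with only the groups compared in the fit. Sex, age and library set differed here as at day 7 of TLR.

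**Figure D4:**
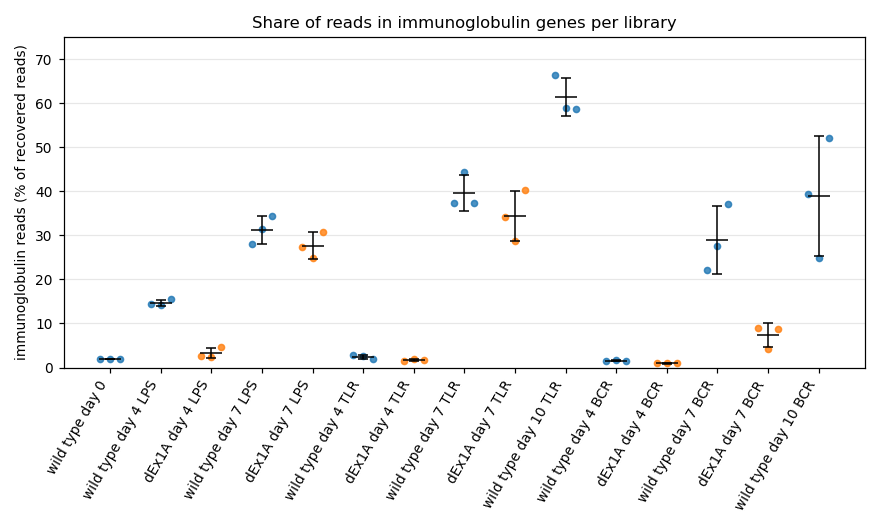
Share of reads from immunoglobulin genes in percent in every group, with 1 point per library in blue for wild type and orange for dEx1A. Black bars give mean ± SD.

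In BCR cultures the change of the genotype difference from day 4 to day 7 was −0.59 ± 0.40 for Prdm1 (adjusted p = 0.261; −1.04, adjusted p = 0.0206 without replicate 2 of dEx1A day 4) and passed for Bach2 (−3.40 ± 0.22), Jchain (−1.63 ± 0.58), Sdc1 (−1.07 ± 0.41) and Xbp1 (−0.84 ± 0.24). Nov (5.98 ± 0.35), Thy1 of the fibroblast list (4.66 ± 0.46) and Tnfrsf8 (4.44 ± 0.28) moved up, and Nxpe2, a secreted glycoprotein (−5.18 ± 0.41), Nuggc (−4.44 ± 0.40) and the carboxypeptidase gene Cpm (−4.16 ± 0.25) down. After the GC and length correction Sdc1 was at −1.69 and Xbp1 at −1.52. With only the groups compared in the fit the calls of Jchain (adjusted p = 0.0819), Sdc1 (0.101) and Xbp1 (0.0694) ended, and that of Sdc1 also with no filter (adjusted p = 0.0557) and voom (adjusted p = 0.0698). Without 1 library the calls of Jchain (−1.23 to −1.58, adjusted p = 0.0534 to 0.112) and Sdc1 (−0.76 to −1.08, adjusted p = 0.0611 to 0.147) each ended in 7 of 12 cases. Cell division moved up in 22 of 28 and down in 0 (23 up adjusted over the list alone, adjusted p = 1.27e-11), with Birc5, survivin, at 1.40 ± 0.19. Mature B cell identity moved down in 17 of 24 and up in 1 (18 and 1 adjusted over the list alone, adjusted p = 3.23e-09), with Ms4a1 at −2.80 ± 0.32. In limma, 3335 genes moved up and 3548 down, 6883 in all, across 2 library sets, and 3981 with only the groups compared in the fit.

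Across all 6 genotype comparisons, which share no libraries, 3 genes were higher and 4 lower in every one, a count made after the values were seen. Car12, a carbonic anhydrase, was higher by 0.92 and 1.55 in LPS at days 4 and 7, 2.11 and 2.34 in TLR and 1.42 and 2.52 in BCR, with Ier5 and the kinase gene Nek6 alongside. Cep85 was lower in the same order at −0.75 and −1.38, −3.11 and −4.40, and −2.85 and −4.22, with Fmn2, Gm42031 and Gm43305. The lists are not independent, since sex and age differed alike in 4 of the 6 comparisons and library set differed in 3, so genes can be shared without an effect of genotype.

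Between culture systems, dEx1A cells at day 4 of LPS were compared with dEx1A cells at day 4 of TLR, both female and from the same library set. Prdm1 was at −0.23 ± 0.28 (adjusted p = 0.536). Nov (−8.99 ± 0.25), the serotonin receptor gene Htr7 (−8.52 ± 0.21), Thy1 of the fibroblast list (−7.50 ± 0.32) and Socs2 (−7.49 ± 0.24) were lower in LPS. The B cell surface genes Ly6d (7.01 ± 0.53), Fcrla (6.67 ± 0.17) and Fcrl5 (5.79 ± 0.22) and the heavy chain gene Ighg2b (5.56 ± 0.48) were higher. Homing and adhesion was higher in 14 of 20 and lower in 2 (14 and 2 adjusted over the list alone, adjusted p = 6.1e-06), with S1pr1 at 2.86 ± 0.18. The mature B cell identity list was higher in 18 of 24 and lower in 3 (18 and 3 adjusted over the list alone, adjusted p = 8.74e-07, adjusted p = 0.075 with an estimated correlation). Fibroblast genes were lower in 12 of 14 and higher in 0 (12 lower adjusted over the list alone), with the matrix protein gene Fn1 at −3.93 ± 0.39 (adjusted p = 1.14e-07, adjusted p = 0.11 with an estimated correlation). In limma, 4285 genes were higher and 4929 lower in LPS.

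At day 7 the dEx1A LPS and TLR cells differed in heavy chain transcripts. Prdm1 was at −0.60 ± 0.28 (adjusted p = 0.155, and 0.0089 with only the groups compared in the fit) and Jchain at −0.44 ± 0.41 (adjusted p = 0.538). Ighe (−6.30 ± 0.29) was lower in LPS, near the floor of detection at 4.35 ± 0.32, and Ighg2b (4.71 ± 0.48) higher. Thy1 of the fibroblast list (−5.92 ± 0.32) and Nov (−5.34 ± 0.25) were lower, and Fcrl5 (4.10 ± 0.22), Bach2 (1.29 ± 0.16) and Pax5 (1.48 ± 0.21) higher. Mature B cell identity was higher in 10 of 24 and lower in 3 (14 and 3 adjusted over the list alone), with Cd72 at 2.01 ± 0.22 (adjusted p = 0.00016, adjusted p = 0.254 with an estimated correlation). Fibroblast genes were lower in 8 of 14 and higher in 0 (9 lower adjusted over the list alone), with Col1a2 at −2.33 ± 0.35 (adjusted p = 8.07e-08, adjusted p = 0.254 with an estimated correlation). In limma, 1583 genes were higher and 1946 lower in LPS, and 2666 and 2487 after the GC and length correction.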

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

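The GC and length tests, the share of other genes set against the macrophage list and all counts of regrouped samples were chosen after the result was seen; the library set, macrophage and chromosome 10 tests were written down before they were run, but the values that led to them, and to the macrophage list and the window of 20 M bases, had been seen.

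The results below stood out because the genotype difference itself was tested between day 4 and day 7 and differed. In LPS this held for 1114 genes, in TLR for 10044 and in BCR for 6883, and in each case the 4 groups lay across the 2 library sets. In LPS, where sex and age were matched, the change was 3.05 for Sdc1, 2.36 for Jchain, 1.56 for Xbp1, 1.61 for Irf4, 4.09 for Igha, 3.07 for Hid1, 3.20 for Gpx3 and 3.34 for Cacna1h. It was −0.99 for Bach2, −2.61 for Fcer2a, −2.12 for Gpr34, −2.23 for Kynu, −1.96 for Yy2 and −5.06 for Rpl6l, a copy of a ribosomal protein gene whose reads are uncertain.

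In TLR the change was −1.67 for Prdm1, −2.59 for Bach2, −1.03 for Pax5, −1.54 for Jchain, −1.11 for Xbp1, −3.30 for Cr2, −3.45 for Gpm6a, −3.51 for Serpinb1a, −3.59 for mt-Atp6 and −5.25 for Rpl6l. It was 6.94 for Anxa2, 6.18 for Junb, 6.64 for Mif, 7.72 for Rpl36 and 6.22 for Rps12l1, and the reads of the last 2 are shared with near-identical copies.

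In BCR it was −3.40 for Bach2, −0.94 for Pax5, −0.71 for Irf4, −1.63 for Jchain, −1.07 for Sdc1, −0.84 for Xbp1, −4.16 for Cpm, −4.53 for Ms4a4c, −4.44 for Nuggc, −5.18 for Nxpe2 and −4.68 for Pde2a. It was 5.98 for Nov, 4.66 for Thy1, 4.44 for Tnfrsf8, 5.23 for Zc3h11a and 4.65 for Rpl36.

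More genes passed in the genotype comparisons between library sets (4957, 11149 and 10330) than within a set (1440, 1469 and 378). A trend with GC content and length is argued against as the whole cause, since 63.4% of the genes called in TLR at day 7 were called in the same direction after the correction. Whether the library set is the main source stays open. LPS day 4 and TLR day 7 lie between the sets in opposite directions, and their corrected differences had a Spearman rho across genes of −0.07 (−0.11 to 0.01 without 1 library), with LPS day 4 and BCR day 7 at 0.11 (0.05 to 0.19), but before the correction −0.35 and −0.18, the direction the set predicts. The 0.11 met the bound set beforehand against the set, above 0.1, but the range without 1 library, added after seeing it, does not hold that bound, and a genotype effect that differs by day, sex or age remains an untested candidate.

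Myeloid genes were higher at day 10 than at day 7 of the BCR culture, with Lyz2 uneven between replicates. RNA from macrophages is a candidate source: of a second list of 24 macrophage genes that shares none with the fixed list, 22 had replicate 3 lowest in day 10 BCR and replicate 2 highest in day 10 TLR, as Lyz2 has (91.7%, against 15.9% of the other genes tested). These genes vary together, so no p is given, and 8 of the 24 averaged above 8 at day 0, so part of the list is not specific to macrophages. The GC trend is argued against as the whole cause, since 9 members of the fixed list were higher after the correction. Expression of these genes by the cultured B-lineage cells themselves would give the same order, was not tested and stays open, and the CD43-based enrichment at the start is a step meant to remove macrophages.

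Amd2, on chromosome 10 within 20 M bases of Prdm1, was higher in dEx1A by 2.83 and 1.88 in LPS, 2.29 in TLR day 4 and 2.39 and 2.17 in BCR, with TLR day 7 at 0.78 (adjusted p = 0.068). A strain or passenger difference near Prdm1 is a candidate explanation: in LPS at day 7, 15.35% of the 241 genes in that window passed against 6.99% elsewhere (one-sided Fisher exact p = 7.06e-06), and in TLR at day 4 14.11% (exact p = 0.000111). The share was 23.24% in LPS day 4 (exact p = 0.697) and 1.66% in BCR day 4 (exact p = 0.618). The evidence is therefore weak, though in LPS day 7 only 5 of 235 genome windows reached 15.35%, up to 28%. Reads shared with Amd1, which lies in the same window, and an effect of Prdm1 on neighbouring genes were not tested.

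Regrouping the same libraries tested whether chance alone could give such counts. For the 20 comparisons of 2 groups the 10 possible splits are too few for a share under 0.05. In wild type the real count and the highest other were 9426 and 0, 7084 and 0, 1599 and 2, and 8970 and 0 for the TLR steps of day 4 against 0, 7 against 4, 10 against 7 and 10 against 0. For the same BCR steps they were 9869 and 0, 5938 and 0, 3253 and 38, and 10207 and 1. For TLR against BCR they were 1476 and 0, 1223 and 1, and 2803 and 2815 at days 4, 7 and 10, and for LPS day 7 against 4 they were 1708 and 4. For the genotypes they were 4957 and 1, and 1440 and 75 in LPS at days 4 and 7, 1469 and 6106, and 11149 and 1 in TLR, and 378 and 46, and 10330 and 174 in BCR. Between dEx1A LPS and TLR they were 9214 and 5240 at day 4 and 3529 and 13 at day 7. In TLR against BCR at day 10 and the TLR genotypes at day 4, 2 of 10 splits reached the real count, and elsewhere 1 did, the real one. The split that called 6106 genes set wild type replicates 1 and 2 and dEx1A replicate 2 of day 4 TLR (GC offsets −0.40 to 0.01) against the other 3 (−1.93 to −1.51). At several times the real 1469 it points to a structure of those samples, which goes with the GC offset and not with genotype. The split with 5240 parted the dEx1A day 4 libraries in the same order of GC offset, −1.93 to −0.68 against −0.40 to 0.35. The split with 2815 genes set day 10 BCR replicates 1 and 2 and TLR replicate 2, the libraries with the highest Lyz2, against the other 3.

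For the interactions the real grouping was set beside 99 others. Counting the real one, at least as many genes passed in 9 of the 100 in LPS (1114 real, 4498 highest other) and in 5 in BCR (6883 and 9171). In TLR it was 2 (10044 and 11590), a share under 0.05. The others were drawn from all regroupings, including those that keep the true genotype split at day 4 or day 7 and so its effect. These shares therefore cannot decide on chance in any culture.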

How the results depend on the processing

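The GC and length correction, alone or with the replicate block, voom and the fit without replicates 1 and 2 of day 10 BCR were chosen after the results were seen. Counts of genes kept within 1.5 times the reported value with no filter, the stricter filter, median centring and the replicate block alone. With only the groups compared in the fit, day 10 against 7 gave 704 genes in TLR and 166 in BCR, TLR against BCR at day 10 gave 1, LPS day 7 against 4 gave 3623, the genotype comparisons 29 in TLR day 4, 103 in BCR day 4 and 6726 in BCR day 7, and the interactions 1923 in LPS and 3981 in BCR. This fit has 4 residual degrees of freedom for 2 groups, and in simulated data it called fewer unchanged genes (2 against 53). After the GC and length correction, day 10 against 7 TLR gave 2800, TLR against BCR 2730, 2246 and 4506 at days 4, 7 and 10, LPS day 7 against 4 3412, the genotype comparisons 2432 in LPS day 7, 2381 in TLR day 4 and 734 in BCR day 4, and the LPS interaction 2072. Mki67 in dEx1A against wild type BCR at day 7 turned from −0.69 to 0.12 (adjusted p = 0.554). With voom, day 10 against 7 TLR gave 1060 and TLR against BCR day 10 1684. Without replicates 1 and 2 of day 10 BCR, day 10 against 7 BCR gave 1480 and TLR against BCR day 10 232. Where nearly as many genes were higher as lower, the larger side turned under some settings, as for the genotypes in LPS day 4 (51.5% higher, 46.7% without replicate 1 of dEx1A). Beyond the fewer samples in the fits that leave some out, the cause was not tested.

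Leaving out 1 library at a time gave 781 to 1517 for day 10 against 7 TLR, 1884 to 4591 for the same step in BCR, and 789 to 1148, 428 to 935 and 650 to 5484 for TLR against BCR at days 4, 7 and 10. It gave 1016 to 1431 for LPS day 7 against 4, 2894 to 4643 for the genotypes in LPS day 4, 479 to 3198 in TLR day 4 and 192 to 369 in BCR day 4, and 628 to 1337 for the LPS interaction. The other 13 counts stayed within 1.5 times. A group left with 1 library was assumed to vary like the others, since limma pools the spread.

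Replicate numbers behaved as a pairing, with each same-numbered correlation above 0.1, in 3 of 23 comparisons: TLR against BCR at days 4 and 10 and the genotypes in BCR day 4. In 0 of these was every sample closest to its own number, and the labels state no pairing. In these 3 the block with the GC correction gave 2725, 4661 and 807.

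Of 488 values of named genes, 485 kept their direction and call with no filter, 479 with median centring, 478 with voom, 460 after the GC and length correction and 429 with only the groups compared, where the calls of 48 ended. Depth limits what could be seen: at 15.17 M to 19.58 M reads in 15 libraries, and with values to 2 decimals, genes near the floor have few reads, and changes of 0.5 log2 units were recovered in 8% of simulated cases.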

Other observations

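Genes and values here were chosen after the results were seen, and each p comes from limma, adjusted within its comparison. In wild type TLR cells Cxcr4, the receptor for the bone marrow chemokine CXCL12, fell from 12.63 ± 0.30 at day 0 to 9.54 ± 0.12 at day 4 and rose again to 11.10 ± 0.02 at day 7 and 12.26 ± 0.02 at day 10. Day 10 read −0.38 against day 0 (adjusted p = 0.19). The dEx1A cells at day 7 had more Cxcr4 than wild type in LPS (1.13, adjusted p = 0.0017) and TLR (1.26, adjusted p = 5.8e-05) and less in BCR (−0.71, adjusted p = 0.013). Ccr10, a receptor for mucosal homing, stood at 8.02 ± 0.31 in dEx1A TLR cells at day 7 against 4.69 ± 0.23 in wild type (3.33, adjusted p = 1.3e-10). At day 7 the TLR and BCR genotypes also differed in sex, age and library set.

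Bach2 moved both ways in wild type cultures. In TLR it read 12.76 ± 0.08 at day 0, 9.90 ± 0.06 at day 4, 10.69 ± 0.07 at day 7 and 9.01 ± 0.38 at day 10, and in BCR 10.24 ± 0.08, 11.31 ± 0.25 and 9.51 ± 0.47 from day 4 to day 10. In dEx1A it was 10.08 ± 0.02 and 8.28 ± 0.35 at days 4 and 7 in TLR, and 10.02 ± 0.08 and 7.68 ± 0.04 in BCR.

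Wild type LPS libraries stood apart in Tnfrsf26, which read 3.04 in 3 of 3 at day 4 and 3.04, 3.86 and 3.67 at day 7. It averaged 8.17 to 10.48 in day 0, TLR and BCR groups of both genotypes and 8.07 and 8.15 in dEx1A LPS. Cep85 was lower in dEx1A in all 6 comparisons. It averaged 12.16 to 15.05 in male wild type groups, 10.66 and 10.86 in female wild type LPS and 9.31 to 9.91 in dEx1A. Sex and age, alike in both LPS genotypes, are argued against for Tnfrsf26. Mouse source, and sex and age for Cep85, were not tested.

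Xist, the transcript of the inactive X chromosome, rose in wild type cultures from male mice, from 4.28 ± 0.03 at day 0 to 6.67 ± 0.42 at day 10 of TLR (adjusted p = 1.2e-07) and 5.98 ± 0.42 at day 10 of BCR (adjusted p = 7.9e-06), against 14.20 to 15.96 on average in groups from female mice.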
